A study of Homo sapiens with 8 samples.

How the data were processed

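RNA of A549 cells, an established line from a human lung adenocarcinoma, was measured on single-colour Agilent arrays. Per the labels, cells received IFN-alpha (10 ng/ml), IFN-beta (500 U/ml), IFN-gamma (10 ng/ml) or a mock treatment, and were harvested after 12 h or 24 h. Equal RNA masses of 3 wells were pooled for each array, so there was 1 array for each of the 4 treatments at each of the 2 times, 8 arrays in all. The arrays lay on 2 slides, per the file headers. Slide 1 held mock at 12 h, IFN-alpha at 12 h, IFN-alpha at 24 h and IFN-gamma at 24 h. Slide 2 held mock at 24 h, IFN-beta at 12 h, IFN-beta at 24 h and IFN-gamma at 12 h.

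The deposited scanner files hold intensity values on a linear scale, made with Agilent Feature Extraction 9.5.3.1, per the file headers. Its processed signal had spatial and multiplicative trends removed within each array and surrogate values set for spots near background, per the file headers, and no scaling between arrays was recorded. Each value of the deposited series matrix lay within 0.497 percent of the processed signal of the same spot. Probe positions are on build hg18 (NCBI36), per the file headers. No genome of that build was at hand, so exons and untranslated regions were not assigned. Of 41000 probes that are not controls, 27778 had a name matched to a reference gene table of assembly GRCh38.p14, which was used for names alone, and 13222 kept the name in the files.

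The processed signal was log2 transformed and the 75th percentile of each array was subtracted. Spots flagged as non-uniform or as population outliers were left out (50 to 83 per array), and the spots of a probe were averaged. Genes were kept if their probe was called well above background on at least 2 arrays. For a gene with several probes, the probe with the highest mean was used. This left 25850 genes, of which 21896 were well above background on all 8 arrays.

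Treatment effects common to both times were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with treatment and time as terms (3 residual and 1.3 prior degrees of freedom). The change of the type I interferon effect (IFN-alpha and IFN-beta as a class) between the times was tested in a model of class by time (2 residual degrees of freedom). Tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. Standard errors (SE) are those of limma. Each test, camera at the preset correlation included, was repeated with slide as a block. The IFN-gamma arrays, the mock arrays and each time are spread evenly over the slides, while both IFN-alpha arrays lie on slide 1 and both IFN-beta arrays on slide 2. In the model of treatment and time the slide term is therefore set by the mock and IFN-gamma arrays. A change of the IFN-gamma effect between the times enters it, and so enters the blocked values of IFN-alpha and IFN-beta. For each interferon and time, genes at 2-fold or more from the mock array of that time were counted without a test. Where a probe was not well above background on any array of a group, its fold is given as a lower bound, with those arrays set to the lowest signal called well above background or to the probe's own value if higher. Files were read and figures drawn with Python 3.11.15 and matplotlib 3.10.9.

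Genes were named by a rule set in advance. For each interferon against mock these are the 20 largest changes that passed and had 1 direction at both times. For the other comparisons they are the 10 largest that passed (5 for the change of the type I effect). The 4 members of each gene list with the largest difference, and a set of signalling and receptor genes that included STAT2, IRF1, IRF9, IFNAR1, IFNAR2, IFNGR1 and IFNGR2, could be named whether or not they passed. Folds, lists, tests, the rule and the other settings were fixed before the data were examined.

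A total of 27 gene lists (572 distinct symbols) were written from general knowledge. They covered antiviral effectors, the ISG15 pathway, nucleic acid sensing, interferon receptors and JAK-STAT signalling, interferon genes, MHC class I and class II antigen processing, guanylate-binding proteins and related GTPases, tryptophan, nitric oxide and nucleotide metabolism, chemokines, cytokines and TNF-family ligands, immune checkpoint and adhesion molecules, complement, cell death, tripartite motif and nuclear body proteins, APOBEC3 enzymes, NF-kB feedback and target genes, proliferation, sterol biosynthesis, hypoxia and glycolysis, endoplasmic reticulum and amino acid stress, heat shock, p53 target genes, NRF2 target genes, lung epithelial markers, leukocyte, fibroblast and endothelial markers, and reference genes. Lists were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Counts of members past the threshold are given over all genes and adjusted over the list alone. At each time the median of a list was set against 10000 random lists of the same size and similar signal.

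The steps were tested on simulated data for IFN-gamma against mock, with 25831 genes and the spread of the real residuals. Of 50 genes changed by each size, the model without slide recovered 11 at a log2 change of 1, 23 at 2, 36 at 4 and 39 at 8, with 7 false calls. With slide differences added and slide as a block it recovered 24, 35, 45 and 50 at these sizes, with 4 false calls. Of 100 unchanged lists, 0 reached an unadjusted camera p under 0.05 in the first setting and 1 in the other. The residuals of simulated genes were drawn independently. This test therefore cannot show how often camera calls unchanged lists whose genes vary together. Camera with an estimated correlation was not run on the simulated data.

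Other settings tried were normexp background correction (offset 50) with quantile normalization, quantile normalization alone, scaling by the median, scaling by the 75th percentile of detected probes, no filter on dim probes, a filter asking for all 8 arrays, the mean of all probes of a gene, flagged spots kept, the series matrix values, slide as a block, eBayes with trend and robust, models without the time or the treatment term, a 2-fold threshold added to the test, 4-fold in place of 2-fold, the mean of both mock arrays, and leaving out each array. The slide block joined with quantile normalization or with the filter on all 8 arrays, and the mock array of the same slide as control, were added after the data were seen. With that control both IFN-alpha arrays are set against mock at 12 h and both IFN-beta arrays against mock at 24 h. Each IFN-gamma array is then set against mock of the other time. A slide difference that varies with signal is not fully removed by this control. The IFN-alpha and IFN-beta doses are in different units and were not converted. No array was left out of the results.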

Results

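Gene expression was measured in A549 cells, a human lung adenocarcinoma line, 12 h and 24 h after treatment with 1 of 3 interferons or a mock treatment. IFN-alpha and IFN-beta are type I interferons and IFN-gamma is the type II interferon. The comparisons ask which genes answer each interferon, how the interferons differ and how the response differs between 12 h and 24 h. Each of the 8 arrays was a pool of 3 wells and there were no replicate arrays, so a p-value here measures the spread between arrays of a treatment after a common time effect, not the spread between cultures. The mock arrays, and the IFN-gamma arrays, lie on different slides. Without the slide block that spread therefore also holds the slide difference and any change of a treatment effect with time. For IFN-gamma against mock the median SE over genes was 0.178, and 0.081 with slide as a block. Between 75.4 and 85.5 percent of spots per array were well above background, the median signal per array was 117 to 179, and the number of arrays limits the precision.

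The slides differed. Dim genes read higher on slide 2, by a median log2 difference of 1.19 in the dimmest 10 percent of genes and of -0.14 in the brightest 10 percent. Between the 2 mock arrays, which lie on different slides, 5145 genes were at 2-fold or more higher at 24 h and 39 lower. Between the IFN-alpha arrays of the 2 times, both on slide 1, the counts were 364 higher and 409 lower, and for IFN-beta, both on slide 2, 209 and 448. Across genes, which are not independent replicates, the correlation r of log2 signals was 0.986 to 0.996 in the 12 pairs of arrays on 1 slide and 0.971 to 0.981 in the 16 pairs across slides. Only IFN-alpha at 12 h and IFN-beta at 24 h could be set against mock of the same time on the same slide.

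**Figure D1:**
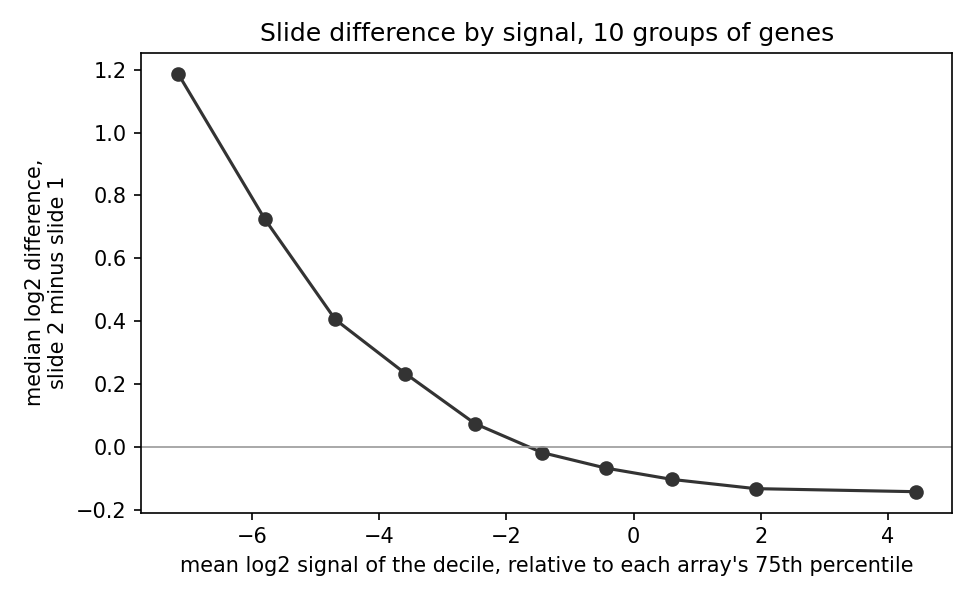
Median log2 difference between the slides (y axis) against mean log2 signal relative to each array's 75th percentile (x axis), each point being 10 percent of the 25850 genes. The difference goes from 1.19 at the dimmest point to -0.14 at the brightest.

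IFN-alpha was set against mock to find the genes that answer it. MX1, a GTPase that blocks virus replication, IFITM1, which hinders virus entry, and IFI27, a classic interferon-induced gene, had the highest values, with log2 differences of 10.22 ± 0.51 (SE, 2 arrays against 2), 10.13 ± 0.48 and 9.53 ± 0.40. None of these passed the threshold (limma adjusted p = 0.0549 for each). Over all genes, 0 of 25850 passed with limma, 1811 had an unadjusted p under 0.05, and LAMP3 had the smallest adjusted p (0.0523) with a log2 difference of 6.94 ± 0.23. Against mock at 12 h on the same slide, MX1 was at 10.42, IFI27 at 8.98, LAMP3 at 6.85 and ISG15 at 6.93. The MX1 probe lies on chromosome 21 at 41752884 to 41752943 and the LAMP3 probe on chromosome 3 at 184322757 to 184322816 (hg18). With slide as a block, 0 genes passed (4094 at an unadjusted p under 0.05), and MX1 was at 10.17 ± 0.62, IFI27 at 9.15 ± 0.17 and LAMP3 at 6.78 ± 0.20. Calls for IFN-alpha depended on the processing: 175 genes passed with normexp and quantile normalization, 90 with quantile normalization, 83 with scaling by the median, 94 among genes well above background on all 8 arrays, 134 with a trended and robust prior, 131 without the time term, 6 with scaling over detected probes and 3 with the mean of all probes.

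The lists show how wide the IFN-alpha difference was. Of 38 antiviral effectors, 36 were higher when adjusted over the list alone, 0 over all genes, and 34 were at 2-fold or more at both times. Their median log2 difference was 4.58, and 4.54 with slide as a block. The camera test called this list (adjusted p = 1.22e-75) but not with an estimated correlation (adjusted p = 0.099 with an estimated correlation). The latter rests on 3 residual degrees of freedom, so it does not decide whether a list changed. In the pathway of ISG15, a ubiquitin-like protein, where ISG15 was at 7.27 ± 0.41, PARP9 at 4.99 ± 0.35, UBA7 at 4.99 ± 0.51 and UBE2L6 at 3.96 ± 0.30, 11 of 12 members were higher adjusted over the list alone (camera adjusted p = 1.58e-28, 0.099 with an estimated correlation). Among 19 genes that sense viral nucleic acids 7 were higher adjusted over the list alone, IFIH1 at 5.83 ± 0.40, IFI16 at 5.24 ± 0.34, RIGI at 5.14 ± 0.45 and DHX58 at 4.89 ± 0.39 (camera adjusted p = 6.38e-18, 0.099 with an estimated correlation). Of 22 genes of MHC class I antigen processing 17 were higher adjusted over the list alone, with a median of 1.72, HLA-F at 3.29 ± 0.46, PSMB8 at 3.11 ± 0.41 and HLA-B at 2.95 ± 0.46 (camera adjusted p = 3.18e-31, 0.110 with an estimated correlation). Probes of the HLA and IFITM genes can bind transcripts of their paralogs, so those values may mix family members.

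Signalling genes and other lists also stood above mock with IFN-alpha. IRF7 was at 5.99 ± 0.33, IRF9 at 3.99 ± 0.15, STAT2 at 2.42 ± 0.34 and IRF1 at 2.02 ± 0.24, and 9 of 35 genes of the receptor and JAK-STAT list were higher adjusted over the list alone (camera adjusted p = 1.65e-15, 0.099 with an estimated correlation). The 2 probes of IRF9 differed, at 2.46 and 3.99. The receptor genes IFNAR1, IFNAR2, IFNGR1 and IFNGR2 were at -0.24, 0.25, 0.23 and 0.09. Among tripartite motif and nuclear body proteins 11 of 16 were higher adjusted over the list alone, TRIM22 at 6.98 ± 0.55 and SP110 at 3.77 ± 0.26 (camera adjusted p = 6.39e-20, 0.099 with an estimated correlation). Of the 8 guanylate-binding proteins and related GTPases 4 were higher adjusted over the list alone, GBP1 at 5.01 ± 0.68 and GBP3 at 3.56 ± 0.39 (camera adjusted p = 1.80e-05, 0.197 with an estimated correlation). The lists of cell death (11 of 31 higher adjusted over the list alone), immune checkpoint and adhesion molecules (7 of 17, LGALS9 at 4.32 ± 0.29), complement (5 of 18, CFB at 4.50 ± 0.35), tryptophan, nitric oxide and nucleotide metabolism (5 of 16, SAMHD1 at 2.96 ± 0.13) and APOBEC3 enzymes (3 of 5) were called by camera, with adjusted p = 0.110, 0.110, 0.099, 0.099 and 0.197 with an estimated correlation. The cytokine list was called as well (camera adjusted p = 0.00103, 0.136 with an estimated correlation), with 2 of 23 higher adjusted over the list alone. Because mock was dim, CASP1 was at least 30.6-fold and IL7 at least 7.79-fold above mock over both times. Among p53 target genes, ZMAT3 was at -1.79 ± 0.26, the 1 member of 15 that was lower adjusted over the list alone (camera adjusted p = 0.264). The 2 probes of LGALS9 differed, at 3.22 and 4.32. Lists without a camera call were MHC class II antigen processing (median -0.41, 1 of 21 higher adjusted over the list alone, adjusted p = 0.639) and chemokines (-0.25, 2 higher and 1 lower of 19, 0.0862). Camera with slide as a block called the chemokines (median 0.29, adjusted p = 0.00502), but not with an estimated correlation and no block (adjusted p = 0.559), and 10 of these 19 were well above background on all 8 arrays. The median of MHC class II antigen processing was -0.01 with the block. With the block 13 of the 19 nucleic acid sensors were higher adjusted over the list alone.

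IFN-beta was set against mock in the same way. Antiviral genes again had the highest values, MX1 at 7.58 ± 0.51 (SE, 2 arrays against 2), IFI27 at 6.40 ± 0.40, and IFIT1, which binds viral RNA, at 5.84 ± 0.64. IRF9, a subunit of the transcription factor that type I interferon activates, was at 3.42 ± 0.15 and had the smallest adjusted p (0.22), so 0 of 25850 genes passed with limma, and 319 had an unadjusted p under 0.05. Against mock at 24 h on the same slide, MX1 was at 6.74, IFI27 at 6.69, IFIT1 at 4.86, ISG15 at 5.12 and IRF9 at 3.17. With slide as a block, 0 genes passed (1237 at an unadjusted p under 0.05), and IFI27 was at 6.78 ± 0.17 and ISG15 at 5.38 ± 0.19. Probes of IRF9 differed here too, at 1.86 and 3.42. With normexp and quantile normalization or with a trended and robust prior 2 genes passed, and 1 without the time term.

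With IFN-beta, 28 of 38 antiviral effectors were higher adjusted over the list alone and 24 were at 2-fold or more at both times. Their median log2 difference was 1.78, and 2.04 with slide as a block (camera adjusted p = 8.26e-61, 0.276 with an estimated correlation). In the ISG15 pathway 10 of 12 were higher adjusted over the list alone, with a median of 1.55 (camera adjusted p = 8.17e-27, 0.276 with an estimated correlation). Among nucleic acid sensors 4 of 19 were (camera adjusted p = 1.71e-07, 0.276 with an estimated correlation), and among tripartite motif and nuclear body proteins 3 of 16, TRIM22 at 2.70 ± 0.55 and SP110 at 2.01 ± 0.26 (camera adjusted p = 1.34e-10, 0.276 with an estimated correlation). Genes of MHC class I antigen processing had a median of 0.46 and 0 of 22 passed adjusted over the list alone, with HLA-F at 0.88 ± 0.46 and B2M at 0.63 ± 0.31 (camera adjusted p = 9.85e-07, 0.490 with an estimated correlation). With slide as a block 10 of these 22 were higher adjusted over the list alone. The GTPase list had a median of 0.43 with 0 of 8 passing adjusted over the list alone (camera adjusted p = 0.00367, 0.490 with an estimated correlation), GBP1 at 1.62 ± 0.68. IRF7 was at 3.91 ± 0.33, STAT2 at 0.84 ± 0.34 and IRF1 at 0.11 ± 0.24. The 2 probes of IRF7 differed, at 2.83 and 3.91. LAMP3 was at 2.43 ± 0.23 and SAMHD1 at 1.33 ± 0.13. The lists of MHC class II antigen processing (median 0.24), chemokines (0.32) and immune checkpoint and adhesion molecules (0.24) had 0 members past the threshold adjusted over the list alone and were called by camera, each with adjusted p = 0.490 with an estimated correlation. Against mock of the same slide their medians at 12 h and 24 h were -0.10 and -0.13, 0.01 and 0.06, and 0.02 and 0.05. Of the MHC class II genes 16 of 21, and of the chemokines 10 of 19, were well above background on all 8 arrays. The lists of receptors and JAK-STAT signalling (median 0.00, 3 of 35 higher adjusted over the list alone), tryptophan, nitric oxide and nucleotide metabolism (0.03, 1 of 16), cytokines (0.09, 0 of 23), complement (-0.02, 0 of 18), cell death (0.01, 0 of 31) and APOBEC3 enzymes (0.04, 0 of 5) were not called. Camera with the slide block called 5 of these 6 as higher, with adjusted p = 0.00309 for receptors and JAK-STAT signalling, 0.00144 for tryptophan, nitric oxide and nucleotide metabolism, 0.00144 for complement, 0.000466 for cell death and 0.0282 for APOBEC3 enzymes, while cytokines had 0.360. In the same order these 5 had adjusted p = 0.509, 0.490, 0.5, 0.680 and 0.859 with an estimated correlation and no block. With the block 2 of 19 nucleic acid sensors were higher adjusted over the list alone.

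IFN-gamma was the interferon with genes past the threshold. ICAM1, an adhesion molecule, rose by 4.62 ± 0.13 on the log2 scale (SE, 2 arrays against 2, adjusted p = 0.0412), and UBD, a ubiquitin-like modifier, by 8.45 ± 0.32 (0.0412). IDO1, which degrades tryptophan, rose by 9.67 ± 0.76 (0.048), the transcription factor IRF1 by 5.35 ± 0.24 (0.0459) and the chemokine CXCL2 by 2.35 ± 0.09 (0.0412). In all, 88 of 25850 genes passed with limma, 78 higher and 10 lower, and 68 of them carry a gene symbol. The ICAM1 probe lies on chromosome 19 at 10257298 to 10257358 and the IDO1 probe, named INDO in the files, on chromosome 8 at 39904686 to 39904745 (hg18). The IFN-gamma and mock arrays are split evenly over the slides, so the estimates are the same with slide as a block. With the block 678 genes passed, 380 higher and 298 lower, and all 88 were among them, with ICAM1 at 4.62 ± 0.11 and an adjusted p of 0.0347. The share of higher genes also moved with normexp and quantile normalization, where 307 rose and 138 fell, and in genes well above background on all 8 arrays with slide as a block, where 915 rose and 1707 fell. The count was 153 with quantile normalization, 222 among genes well above background on all 8 arrays, 328 with a trended and robust prior, 259 without the time term and 29 with the mean of all probes. No gene passed when any 1 of the 8 arrays was left out, or without the filter on dim probes (2945 at an unadjusted p under 0.05), and 3058 had an unadjusted p under 0.05 in the full fit.

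Other large IFN-gamma changes that passed were in SECTM1 (5.91 ± 0.34), TNFRSF14 (5.76 ± 0.41), SAMD9L (5.49 ± 0.45), PLAAT4 (5.36 ± 0.38), GBP3 (5.23 ± 0.39), GBP2 (4.88 ± 0.28), APOL6 (4.65 ± 0.30), TRIM31 (4.56 ± 0.33), IFITM1 (6.41 ± 0.48) and BATF2 (6.31 ± 0.49). The 3 probes of SECTM1 ranged from 1.04 to 5.91. Genes that were dim in mock rose at least 35.0-fold (IL7), at least 32.1-fold (GIMAP2) and at least 7.88-fold (IRF8). BST2 rose by 6.54 ± 0.48 with a bound of 87.0-fold at 12 h, where the mock array was dim and lay on the other slide. Dim genes read lower on that slide, so part of this bound may be the slide difference.

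In MHC class I antigen processing 4 of 22 genes rose over all genes and 19 adjusted over the list alone, with a median of 2.26 (camera adjusted p = 6.18e-29, 0.106 with an estimated correlation). The peptide transporter gene TAP1 rose by 3.85 ± 0.27 and the immunoproteasome gene PSMB9 by 3.58 ± 0.29, while PSMB8 was at 3.86 ± 0.41 (adjusted p = 0.0656) and ERAP2 at 3.25 ± 0.29 (adjusted p = 0.0535). Among 8 guanylate-binding proteins and related GTPases, which act against intracellular pathogens, 2 rose over all genes and 5 adjusted over the list alone, with a median of 5.04 (camera adjusted p = 1.14e-09, 0.106 with an estimated correlation). GBP1 was at 7.75 ± 0.68 (adjusted p = 0.0517). In MHC class II antigen processing CTSS rose by 3.11 ± 0.25, the 1 of 21 past the threshold over all genes, while 3 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.000336, 0.224 with an estimated correlation). IFI30 was at 3.19 ± 0.33. CD74 was at 2.41 ± 0.45. Its bound at 12 h was 3.93-fold above mock, but that mock array lies on the other slide, where dim genes read lower, so part of it may be the slide difference. CIITA was at 1.57 ± 0.54, and its 4 probes ranged from 0.67 to 6.08. In tryptophan, nitric oxide and nucleotide metabolism IDO1 and SAMHD1 (2.45 ± 0.13) rose over all genes and 10 of 16 adjusted over the list alone (camera adjusted p = 3.73e-15, 0.106 with an estimated correlation). WARS1, the tryptophan tRNA ligase, was at 3.75 ± 0.32 (adjusted p = 0.0503). PSMB8, ERAP2, GBP1, IFI30 and WARS1 passed with slide as a block, with adjusted p of 0.0347 to 0.0447. With the block 17 of the MHC class I genes, 4 of the GTPases, 2 of the MHC class II genes and 7 of the tryptophan, nitric oxide and nucleotide metabolism genes rose over all genes.

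Antiviral and signalling genes also answered IFN-gamma. Of 38 antiviral effectors 6 rose over all genes and 34 adjusted over the list alone, with a median of 2.89 (camera adjusted p = 9.00e-49, 0.106 with an estimated correlation). In the ISG15 pathway 4 of 12 rose over all genes, among them UBE2L6 by 4.45 ± 0.30 and PARP9 by 4.68 ± 0.35, and 10 adjusted over the list alone (camera adjusted p = 6.83e-19, 0.106 with an estimated correlation). In the receptor and JAK-STAT list 7 of 35 rose and 1 fell over all genes, 19 rose and 2 fell adjusted over the list alone, and IRF9 rose by 3.43 ± 0.15 (camera adjusted p = 1.67e-14, 0.106 with an estimated correlation). Here the 2 IRF9 probes were at 2.15 and 3.43. STAT2 was at 1.77 ± 0.34 and did not pass. Of the nucleic acid sensors TLR3 rose by 4.31 ± 0.33, the 1 of 19 past the threshold, against 7 adjusted over the list alone (camera adjusted p = 2.69e-12, 0.106 with an estimated correlation). Among tripartite motif and nuclear body proteins SP140 rose by 2.98 ± 0.20, the 1 of 16 past the threshold, against 10 adjusted over the list alone (camera adjusted p = 2.92e-14, 0.106 with an estimated correlation), and TRIM22 was at 6.55 ± 0.55. SP140 had 2 probes, at 1.35 and 2.98. When slide was a block 16 antiviral effectors, 8 genes of the ISG15 pathway, 11 receptor and JAK-STAT genes (1 fell), 4 nucleic acid sensors and 7 tripartite motif and nuclear body proteins rose over all genes. IFNAR1, IFNAR2, IFNGR1 and IFNGR2 were at -0.11, 0.51, -0.03 and -0.29.

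The remaining immune lists were called for IFN-gamma by camera at the preset correlation. Over all genes and adjusted over the list alone, 4 and 13 of 31 cell death genes were higher, 2 and 11 of 17 immune checkpoint and adhesion molecules, 2 and 8 of 19 chemokines, 1 and 8 of 23 cytokines and TNF-family ligands, 1 and 8 of 18 complement genes, and 0 and 1 of 5 APOBEC3 enzymes. Adjusted over the list alone 3 chemokines, 1 cell death gene, 1 immune checkpoint or adhesion molecule and 1 complement gene were lower. Their adjusted p was 0.137, 0.106, 0.234, 0.106, 0.106 and 0.234 with an estimated correlation. C1R rose by 3.51 ± 0.21, while CFB was at 4.18 ± 0.35 and CD274 at 3.86 ± 0.37 without passing. Under the slide block 9 cell death genes, 10 immune checkpoint and adhesion molecules, 4 chemokines (1 fell), 5 cytokines, 7 complement genes and 1 APOBEC3 enzyme rose over all genes. Against dim mock arrays CASP1 was at least 116-fold, SERPING1 at least 29.7-fold and CXCL10 at least 10.9-fold higher, also without passing. APOL3 had a bound of 576-fold above mock at 12 h, but that mock array lies on slide 1, where dim genes read lower. On slide 2 its log2 signal was 2.13 with IFN-gamma at 12 h and -6.21 with mock at 24 h. The 2 probes of APOL3 gave 4.94 and 10.18 over both times.

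**Figure D2:**
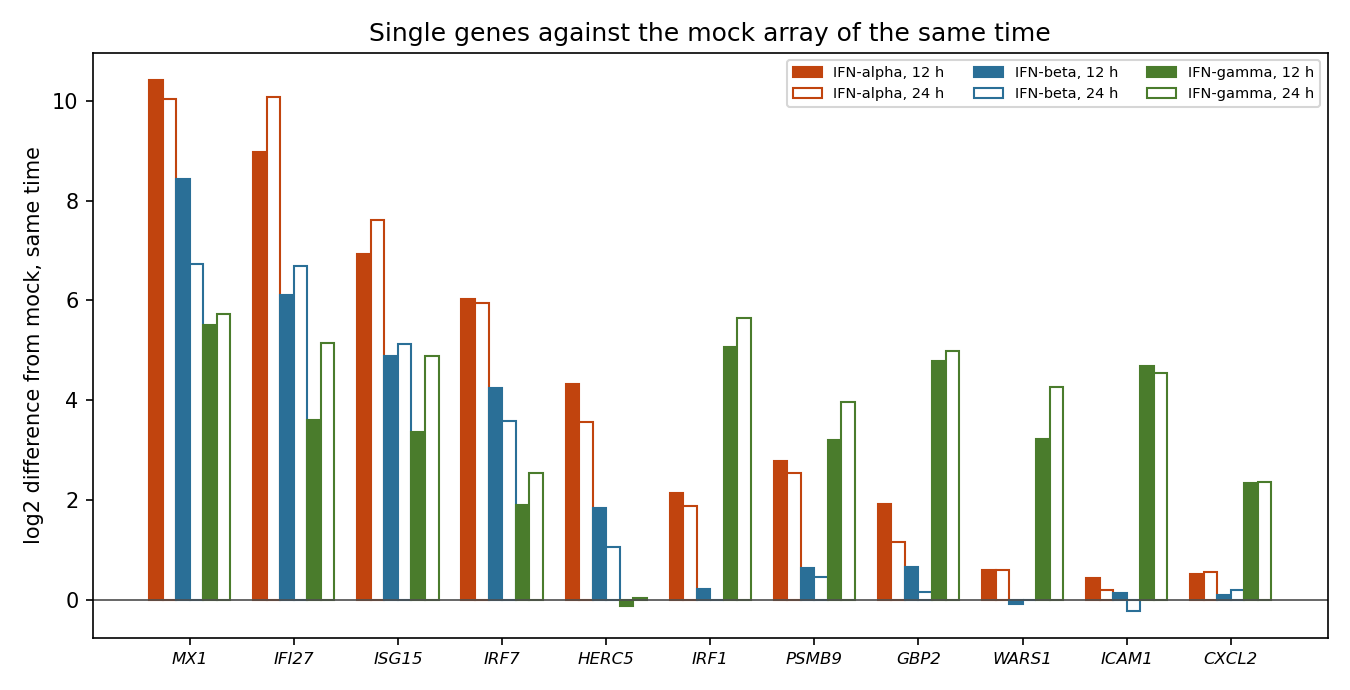
Log2 difference from the mock array of the same time (y axis) for 11 genes (x axis), with filled bars for 12 h and open bars for 24 h, 1 array each. MX1 is at 10.42 with IFN-alpha, 8.43 with IFN-beta and 5.50 with IFN-gamma at 12 h, and ICAM1 is at 0.45, 0.13 and 4.68.

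Reference genes, proliferation genes and most stress lists lay close to mock. Reference genes had medians of 0.02 with IFN-alpha, -0.12 with IFN-beta and 0.02 with IFN-gamma, and 0 of 16 members passed in any of these, over all genes or adjusted over the list alone. Proliferation genes had medians of -0.01, -0.11 and -0.04 with 0 of 36 passing either way. The IFN-beta value was called by camera (adjusted p = 0.000607, 0.509 with an estimated correlation) but was -0.01 with slide as a block. MKI67 was at -0.37 ± 0.11 and TOP2A at -0.27 ± 0.11 with IFN-alpha. Medians with IFN-alpha, IFN-beta and IFN-gamma were 0.00, -0.05 and 0.04 for heat shock, 0.04, -0.10 and -0.06 for NRF2 targets, -0.07, -0.17 and -0.18 for p53 targets, 0.16, -0.11 and 0.12 for hypoxia and glycolysis, and 0.07, -0.18 and -0.11 for endoplasmic reticulum and amino acid stress. In that last list 1 of 19 members, ATF3 at 1.51 ± 0.13, was higher with IFN-gamma adjusted over the list alone. Apart from ATF3 and ZMAT3, 0 members of these 5 lists passed without the slide block, over all genes or adjusted over the list alone. With the block and IFN-gamma, 4 hypoxia and glycolysis genes were higher and 6 lower adjusted over the list alone (1 lower over all genes), 5 stress genes were lower against 1 higher, and 3 p53 targets were lower. Sterol biosynthesis genes had medians of 0.03, -0.05 and -0.27, the IFN-gamma value called by camera (adjusted p = 0.00501, 0.570 with an estimated correlation). NF-kB feedback and target genes had medians of 0.22, -0.11 and 0.13, with 0 and 0 of 18 past the threshold with IFN-alpha and IFN-beta and 2 higher and 1 lower with IFN-gamma, adjusted over the list alone. Of the 8 interferon genes measured 3, IFNA4, IFNE and IFNL2, were well above background on all 8 arrays, so no value is given for that list. Lung epithelial markers had medians of -0.25, 0.24 and -0.01, and of these 22 LAMP3 rose with IFN-gamma by 3.18 ± 0.23 while KRT19 was at -0.96 ± 0.18. Adjusted over the list alone, 2 of these markers were higher with IFN-alpha, 1 with IFN-beta, and 3 higher and 1 lower with IFN-gamma. Leukocyte, fibroblast and endothelial markers had medians of -0.78, 0.50 and 0.05, and of -0.11, 0.00 and 0.05 with slide as a block, and 8 of these 16 were well above background on all 8 arrays.

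Camera called several of these lists at the preset correlation and none with an estimated correlation. With IFN-alpha these were NF-kB (adjusted p = 0.219 with an estimated correlation), hypoxia and glycolysis (0.353), sterol biosynthesis (0.577), endoplasmic reticulum and amino acid stress (0.551) and leukocyte, fibroblast and endothelial markers (0.552). With IFN-beta they were p53 targets (adjusted p = 0.398 with an estimated correlation), NRF2 targets (0.276), endoplasmic reticulum and amino acid stress (0.5), lung epithelial markers (0.490), leukocyte, fibroblast and endothelial markers (0.509) and reference genes (0.490). With IFN-gamma they were NF-kB (adjusted p = 0.369 with an estimated correlation) and p53 targets (0.234). All 6 of these IFN-beta calls were lost with slide as a block (adjusted p from 0.119 for NRF2 targets to 0.995), and the median of lung epithelial markers was -0.08. For IFN-alpha the block ended the calls of sterol biosynthesis (adjusted p = 0.538), endoplasmic reticulum and amino acid stress (0.788) and leukocyte, fibroblast and endothelial markers (0.186). Called with the block alone were proliferation (median -0.10, adjusted p = 0.00774) and p53 targets (-0.16, 0.0257), both lower with IFN-alpha, and hypoxia and glycolysis (0.04, 0.008), higher with IFN-beta, with adjusted p = 0.885, 0.552 and 0.752 with an estimated correlation and no block. Over all genes the median difference was -0.10 with IFN-alpha, and scaling by the median of each array moved that of IFN-beta from -0.01 to -0.10.

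The direct comparison of IFN-alpha with IFN-beta asks whether these type I interferons had equal effects at the doses used, which are given in different units. Antiviral genes were higher with IFN-alpha, but 0 of 25850 genes passed with limma (2194 at an unadjusted p under 0.05, smallest adjusted p = 0.379), and 0 with slide as a block. The RNA-binding antiviral gene IFIT2 was at 4.64 ± 0.44 (SE, 2 arrays against 2), IFITM1 at 4.54 ± 0.48, LAMP3 at 4.51 ± 0.23, TRIM22 at 4.27 ± 0.55 and HERC5 at 2.49 ± 0.31, while IRF9 was at 0.56 ± 0.15. Of 38 antiviral effectors 35 were higher with IFN-alpha adjusted over the list alone, with a median of 2.62 (camera adjusted p = 8.22e-32, 0.205 with an estimated correlation). All IFN-alpha arrays lay on slide 1 and all IFN-beta arrays on slide 2, so part of each value is the slide difference. With slide as a block that median was 2.08 and 37 of 38 members were higher with IFN-alpha. The slide term comes from the mock and IFN-gamma arrays, so a change of the IFN-gamma effect between the times enters these blocked values. Set each against the mock array of its own slide, the antiviral median was 4.77 at 12 h and 4.87 at 24 h with IFN-alpha, and 2.14 and 1.46 with IFN-beta. A slide difference that varies with signal may remain here, since IFN-alpha is then measured on slide 1 and IFN-beta on slide 2. For the ISG15 pathway, MHC class I and GTPase lists 11 of 12, 17 of 22 and 4 of 8 members were higher with IFN-alpha adjusted over the list alone, with adjusted p = 0.205, 0.205 and 0.355 with an estimated correlation. These counts with slide as a block were 11 of 12, 14 of 22 and 0 of 8, the GTPase median being 1.35 against 1.31 without it. HLA-B was at 2.34 ± 0.46 (1.48 ± 0.30 with slide as a block), CCL5 at 2.75 ± 0.39 (2.02 ± 0.24) and IRF1 at 1.90 ± 0.24 (1.61 ± 0.29). The lists of nucleic acid sensing, receptors and JAK-STAT signalling, cell death, tripartite motif and nuclear body proteins, complement, immune checkpoint and adhesion molecules, and tryptophan, nitric oxide and nucleotide metabolism were also called by camera in this direction, each with adjusted p = 0.205 with an estimated correlation. All 7 calls at the preset correlation held with slide as a block, while the number of members higher adjusted over the list alone went from 8 to 1 of 35 for receptors and JAK-STAT signalling and from 10 to 0 of 31 for cell death. The calls were not limited to lists of the interferon response, 21 of 27 lists being called at the preset correlation. Among these were hypoxia and glycolysis (median 0.26, adjusted p = 4.89e-05), NRF2 targets (0.13, 0.00268), endoplasmic reticulum and amino acid stress (0.25, 0.00272), reference genes (0.16, 0.00917) and sterol biosynthesis (0.10, 0.0289), with adjusted p = 0.355, 0.205, 0.387, 0.355 and 0.666 with an estimated correlation. Each of these 5 calls was lost with slide as a block, and so was that of leukocyte, fibroblast and endothelial markers, lower with IFN-alpha (median -1.08, adjusted p = 0.422 with an estimated correlation). Proliferation was called higher (median 0.11, adjusted p = 0.0118, 0.667 with an estimated correlation) and with the block lower (-0.09). Cytokines, APOBEC3 enzymes and NF-kB were called with and without the block, with adjusted p = 0.253, 0.262 and 0.240 with an estimated correlation. Without the time term 1 gene passed.

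The type I interferons as a mean were then set against IFN-gamma to separate the classes. ICAM1 was lower with type I interferon by a log2 difference of -4.48 ± 0.11 (SE, 4 arrays against 2, adjusted p = 0.0254) and PRRT2 by -2.85 ± 0.10 (adjusted p = 0.0493), and these were the 2 of 25850 genes that passed with limma (2564 at an unadjusted p under 0.05). ICAM1 was at 0.45 and 0.20 with IFN-alpha and at 0.13 and -0.23 with IFN-beta, at 12 h and 24 h. The PRRT2 probe lies on chromosome 16 at 29734440 to 29734499 (hg18). Slides are balanced in this comparison, and with slide as a block 239 genes passed, 89 higher and 150 lower with type I interferon, both of these genes included. With normexp and quantile normalization 261 passed, 82 higher and 179 lower, and among genes well above background on all 8 arrays 54 passed, 15 higher and 39 lower. The count was 11 with quantile normalization, 4 with scaling by the median, 129 with a trended and robust prior, 122 without the time term and 1 without the filter on dim probes. Neither gene passed when any 1 of the 8 arrays was left out.

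Of the genes that did not pass, IFIT1 was at 4.02 ± 0.55, IFI27 at 3.59 ± 0.35, MX1 at 3.28 ± 0.44, HERC5 at 2.74 ± 0.27 and IRF7 at 2.73 ± 0.28, each higher with type I interferon. HERC5 was at -0.13 and 0.04 with IFN-gamma. Lower with type I interferon were IDO1 (-7.55 ± 0.66), IRF1 (-4.29 ± 0.21), GBP2 (-3.91 ± 0.24), IL18BP (-3.99 ± 0.44), WARS1 (-3.47 ± 0.27), TAP1 (-2.30 ± 0.23) and CXCL2 (-2.01 ± 0.08). The 2 probes of IL18BP gave 1.80 and 4.71 for IFN-gamma against mock. The type I value is a mean of unlike responses. Each array was set against mock of its own slide, at 12 h and 24 h. MHC class I medians were then 1.75 and 1.82 with IFN-alpha, 0.45 and 0.38 with IFN-beta, and 1.77 and 2.84 with IFN-gamma. Antiviral medians were 4.77 and 4.87, 2.14 and 1.46, and 2.32 and 3.52 in that order. A class difference therefore also holds that between IFN-alpha and IFN-beta. Adjusted over the list alone, 12 of 22 MHC class I genes were lower with type I interferon (median -1.02), 5 of 8 GTPases (median -3.39), 16 of 35 receptor and JAK-STAT genes against 5 higher, and 7 of 17 immune checkpoint and adhesion molecules against 1 higher. Adjusted p was 0.313, 0.295, 0.313 and 0.295 with an estimated correlation. Of the antiviral effectors 6 were higher and 2 lower adjusted over the list alone, with a median of 0.44 (camera adjusted p = 0.00547, 0.713 with an estimated correlation). In the ISG15 pathway 4 members were higher and 4 lower adjusted over the list alone, with a median of -0.01 (camera adjusted p = 0.824). Adjusted over the list alone, 7 of 16 genes of tryptophan, nitric oxide and nucleotide metabolism were lower with type I interferon, 8 of 18 complement genes against 1 higher, 13 of 31 cell death genes against 1 higher and 7 of 19 chemokines against 3 higher, with adjusted p = 0.295, 0.295, 0.407 and 0.511 with an estimated correlation. Camera also called MHC class II antigen processing (median -0.17), cytokines (-0.17) and tripartite motif and nuclear body proteins (-0.06) as lower and sterol biosynthesis (0.19) as higher, with adjusted p = 0.427, 0.295, 0.639 and 0.582 with an estimated correlation, and the calls of cytokines and tripartite motif proteins were lost with the block. Adding the slide block, 18 MHC class I genes and 12 genes of tryptophan, nitric oxide and nucleotide metabolism were lower adjusted over the list alone.

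**Figure D3:**
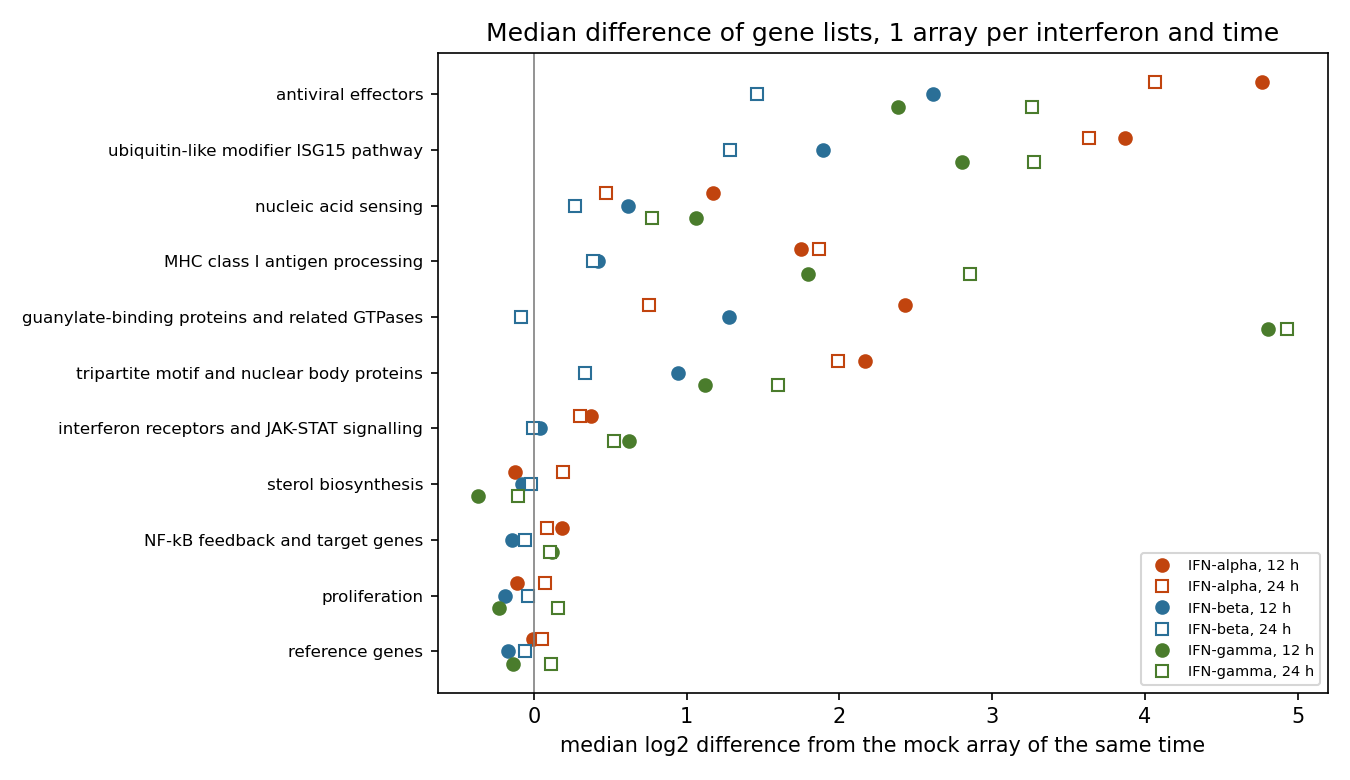
Median log2 difference from the mock array of the same time (x axis) for 11 gene lists (y axis), with filled circles for 12 h and open squares for 24 h, 1 array each. The antiviral median is at 4.77 and 4.07 with IFN-alpha, 2.62 and 1.46 with IFN-beta, and 2.38 and 3.26 with IFN-gamma.

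Time was compared over all treatments, 4 arrays at 24 h against 4 at 12 h, balanced over the slides. Sterol biosynthesis genes were higher at 24 h, with INSIG1 at 1.00 ± 0.17 (SE) and DHCR7 at 0.68 ± 0.12, but 0 of 25850 genes passed with limma (1670 at an unadjusted p under 0.05) and 0 with slide as a block (5273). Of the 24 sterol genes 15 were higher adjusted over the list alone, with a median of 0.39 (camera adjusted p = 2.47e-23, 0.479 with an estimated correlation). Between arrays of 1 slide, 23 of 24 were higher at 24 h with IFN-alpha (median 0.57) and 24 of 24 with IFN-beta (median 0.32). NF-kB feedback and target genes were lower at 24 h, with a median of -0.345, 9 of 18 adjusted over the list alone, TRAF1 at -1.03 ± 0.16, BIRC3 at -0.75 ± 0.16, NFKBIE at -0.69 ± 0.11 and TNFAIP3 at -0.54 ± 0.11 (camera adjusted p = 2.13e-10, 0.479 with an estimated correlation). On 1 slide, 18 of 18 were lower with IFN-alpha and 16 of 18 with IFN-beta. CXCL2 was at -0.57 ± 0.06 and CCL2 at -0.93 ± 0.17. Camera called 9 of 27 lists for time, also MHC class I (median 0.26), complement (0.27), hypoxia and glycolysis (0.08) and proliferation (0.08) as higher and tripartite motif and nuclear body proteins (-0.19), heat shock (-0.09) and receptors and JAK-STAT signalling (-0.10) as lower. With an estimated correlation adjusted p was 0.479 for complement and heat shock and 0.832 for the rest of these.

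The type I effect at 24 h was set against that at 12 h to see whether it grew or faded. The antiviral list had a median change of -0.50 with 0 of 38 passing, over all genes or adjusted over the list alone (camera adjusted p = 0.935), and 0 of 25850 genes passed with limma (388 at an unadjusted p under 0.05, 2206 with slide as a block). The mock arrays of the 2 times lie on different slides, while the arrays of each type I interferon share a slide. Every value of this comparison without the block therefore holds the slide difference between the mock arrays. Of the 388 genes 374 were lower and 14 higher. These values alone do not show whether the response grew or faded. In this model the slide block takes up the difference between IFN-alpha and IFN-beta, so its antiviral median of -2.53 does not remove the slide. Between arrays of 1 slide, the antiviral median at 24 h minus 12 h was -0.09 with IFN-alpha and -0.58 with IFN-beta, where 26 of 38 members were lower. For the GTPases these medians were -0.78 and -0.41. Proliferation genes were called by camera (median 0.16, adjusted p = 0.000607, 0.970 with an estimated correlation, 0.0654 with slide as a block).

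Counts of genes at 2-fold or more from mock of the same time, without a test, show the same slide pattern. On 1 slide, IFN-alpha at 12 h had 775 genes higher and 273 lower, and IFN-beta at 24 h 231 and 543. Across slides there were 390 and 5138 with IFN-alpha at 24 h, 4428 and 37 with IFN-beta at 12 h, 5256 and 248 with IFN-gamma at 12 h and 557 and 5282 with IFN-gamma at 24 h. Against the mock array of the same slide, which is of the other time, these were 819 and 461, 152 and 129, 505 and 309, and 849 and 709. With normexp and quantile normalization IFN-alpha at 12 h had 244 and 15, IFN-alpha at 24 h 239 and 920, IFN-beta at 24 h 49 and 10, and IFN-gamma at 24 h 376 and 788. With quantile normalization alone IFN-alpha at 24 h had 857 and 2907, IFN-beta at 12 h 2356 and 361, IFN-beta at 24 h 323 and 376, IFN-gamma at 12 h 3070 and 999, and IFN-gamma at 24 h 1004 and 2480. At both times alike, 304 genes were higher and 157 lower with IFN-alpha, 137 and 5 with IFN-beta, and 385 and 110 with IFN-gamma. Among genes well above background on all 8 arrays these were 235 and 21, 68 and 0, and 297 and 75.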

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

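The slide, dose and time tests below were chosen after the values were seen, while the splits of the arrays were set in advance. List medians against mock had opposite signs at 12 h and 24 h in 8 of 27 lists with IFN-alpha, 8 with IFN-beta and 10 with IFN-gamma, differences that were not tested. The largest was in MHC class II antigen processing with IFN-gamma, at 1.65 and -0.60. Against the mock array of its own slide, which is of the other time, that list was at -0.05 at 12 h and 0.47 at 24 h. A pair of the lists with opposite signs also lay among the outer 2.5 percent of random lists of like signal on opposite sides at the 2 times. With IFN-gamma the lung epithelial markers had a median log2 difference of 0.85 at 12 h and -0.89 at 24 h. Against the mock array of its own slide each of these was near 0, at -0.04 and 0.04. With IFN-alpha the sterol biosynthesis genes had medians of -0.13 at 12 h and 0.19 at 24 h, and between those arrays, which share a slide, the 24 h median was higher by 0.57.

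Between 4465 and 5839 genes were at 2-fold or more from mock where the arrays lay on different slides. The response to the interferon as the main source is contradicted, since against the mock array of the same slide the 4 counts fell to 1558 at most. A constant amount added to every spot of slide 2 was not seen in the processed signal. The median of negative control spots was higher on slide 2 by 0.166 signal units. It was lower by 0.183 without the IFN-beta 24 h array, whose own median was 2.98. The 25th percentile of other spots was higher on slide 2 by 11.4. Trend removal and surrogate values for spots near background came before these values and could hide such an amount in the control spots. Their raw signal was not examined, so this explanation is not excluded. A slide difference at low signal stays open as an explanation: the 2 mock arrays alone differed at 2-fold or more in 5184 genes, against 773 at most for 2 arrays of a treatment on 1 slide. The mock arrays also differ in time, which may add to that count. Of the mock genes 5145 were higher and 39 lower at 24 h, on slide 2. Between the IFN-gamma arrays, where 24 h lies on slide 1, 184 genes were higher and 4716 lower at 24 h. The direction followed the slide, which argues against a time effect common to these treatments as the main source.

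Antiviral genes were lower with IFN-beta than with IFN-alpha. The slides as the whole cause are contradicted. Against mock of the same time on the same slide, the antiviral median was 4.77 with IFN-alpha at 12 h and 1.46 with IFN-beta at 24 h. Against mock of the other time on the same slide it was 4.87 with IFN-alpha at 24 h and 2.14 with IFN-beta at 12 h. Against mock of the same time on the other slide these 2 arrays had medians of 4.07 and 2.62. The slide difference varies with signal, so it may form part of the gap with either control. The median difference was 2.08 with slide as a block, against 2.62 without it, and 37 of 38 members kept the direction. That block alone cannot decide. Its slide term rests on the mock and IFN-gamma arrays and takes up any change of the IFN-gamma effect between the times. The values also argue against a single factor that scales every log2 difference of IFN-alpha. Each interferon was set against the mock array of its own slide, which its arrays at both times share. The slide difference varies with signal, so part of it may remain in the ratios. The ratio of the IFN-beta to the IFN-alpha difference then had a median of 0.497 over 34 antiviral genes, 0.248 over 18 MHC class I genes and 0.180 over 5 GTPases, the lowest of the 5 lists with a median IFN-alpha difference of at least 1. The ISG15 pathway, at 0.556 over 11 genes, and tripartite motif and nuclear body proteins, at 0.343 over 10, lay within 1.5 times of the antiviral ratio. Over genes at 2-fold or more with IFN-alpha at each time, the antiviral, MHC class I and GTPase ratios were 0.602, 0.260 and 0.226 at 12 h and 0.397, 0.224 and 0.115 at 24 h. A lower effective dose of IFN-beta with a different dose curve for each gene, or a difference between the interferons themselves, may remain, and neither was tested because each interferon had 1 dose.

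With IFN-beta the antiviral genes were closer to mock at 24 h than at 12 h, the list median falling by 1.16. The IFN-beta array at 24 h stood apart on its slide, with 78.7 percent of spots well above background against 84.8 to 85.5 percent on the other 3 arrays, and the fall rests on it. Between the IFN-beta arrays themselves, which share a slide, the median of the member differences was -0.579 and 26 of 38 members were lower. With both set against mock at 24 h on that slide, the list median went from 2.14 to 1.46. The slides of the mock arrays and a fading response cannot be told apart as the source of the rest, since mock at 12 h and at 24 h lie on different slides, and the state of the IFN-beta 24 h array was not tested as a source of any of it.

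For 24 h against 12 h, where 0 genes passed with limma (1670 at an unadjusted p under 0.05), the count of other splits decides nothing, since any split gives at least 0 genes (32 of the 32 that could be fitted). The highest other count was 7942, from the split that follows the slides and the split equal to it once treatment is in the model. That split calls many genes, which points to the slides as a structure of these arrays. With slide as a block the time comparison gave 0 genes (5273 at an unadjusted p under 0.05).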

How the results depend on the processing

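The joined settings and the mock array of the same slide were chosen after the data were seen, and all other settings before. The cause of a moved count was not tested, except that the mean of all probes, the filters and the higher fold change which genes can be counted. Dim genes limit the counts, since 75.4 to 85.5 percent of spots per array were well above background. Each treatment and time had 1 array. In a fit without an array the lone array of that treatment is assumed to vary like the others.

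In the settings used above, genes past the threshold numbered 0 for IFN-alpha, 0 for IFN-beta and 88 for IFN-gamma against mock, 0 for IFN-alpha against IFN-beta, 2 for type I interferons against IFN-gamma and 0 for time. In the order IFN-alpha, IFN-beta, IFN-gamma and type I against IFN-gamma, normexp with quantile normalization gave 175, 2, 445 and 261, a trended and robust prior 134, 2, 328 and 129, and the model without the time term 131, 1, 259 and 122, with 1 for IFN-alpha against IFN-beta. In the order IFN-alpha, IFN-gamma and type I against IFN-gamma, quantile normalization gave 90, 153 and 11, and genes well above background on all 8 arrays 94, 222 and 54. Scaling by the median gave 83 for IFN-alpha and 4 for type I against IFN-gamma. Scaling by the 75th percentile of detected probes gave 6 for IFN-alpha, and the mean of all probes 3 for IFN-alpha and 29 for IFN-gamma. The slide block gave 678 for IFN-gamma and 239 for type I against IFN-gamma. Without a filter these were 0 (2945 at an unadjusted p under 0.05, limma) and 1. Leaving out each array gave 0 to 0 for IFN-gamma and 0 to 0 for type I against IFN-gamma, and the change of the type I effect could not be fitted without either mock array. Quantile normalization with the slide block gave 12 for IFN-alpha, 1026 for IFN-gamma and 579 for type I against IFN-gamma. The filter on all 8 arrays with the slide block gave 278 for IFN-alpha, 6 for IFN-beta, 2622 for IFN-gamma, 1617 for type I against IFN-gamma and 1 for time. Of the 88 genes, 79 passed with normexp, 73 with quantile normalization, 78 with the filter on all 8 arrays, 82 with the trended prior, 80 without the time term, 62 with scaling by the median and 28 with the mean of all probes. Flagged spots kept left all counts unchanged, and the series matrix gave 87 for IFN-gamma.

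Genes at 2-fold or more from mock numbered 1048 and 5528 with IFN-alpha, 4465 and 774 with IFN-beta, and 5504 and 5839 with IFN-gamma, at 12 h and 24 h. In this order normexp with quantile normalization gave 259, 1159, 790, 59, 1138 and 1164, the filter on all 8 arrays 392, 3055, 2369, 184, 3173 and 3136, 4-fold in place of 2-fold 278, 1567, 1069, 101, 1469 and 1424, and the mean of both mock arrays 2022, 2302, 1061, 1355, 1945 and 2427. Quantile normalization gave 2717 for IFN-beta at 12 h and 3484 for IFN-gamma at 24 h, and no filter 1685 for IFN-alpha at 12 h and 1428 for IFN-beta at 24 h. Against the mock array of the same slide the counts were 1280 for IFN-alpha at 24 h, 281 for IFN-beta at 12 h, and 814 and 1558 for IFN-gamma at 12 h and 24 h.

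Of the values of named genes, and of lists called by camera judged by the camera direction, 3317 kept their direction and side of the threshold, 399 came to pass, 452 no longer passed and 8 reversed. Leaving out each array, IFNGR1 with IFN-gamma (-0.0253 with all arrays) ranged from -0.1132 to 0.0625 and was also positive, at 0.0623, without IFN-gamma at 12 h, and IRF1 with IFN-beta (0.1111 with all arrays) ranged from -0.0459 to 0.2681. The proliferation median was -0.0132 for IFN-beta against mock and -0.0873 for IFN-alpha against IFN-beta with the slide block, and 0.007 for the latter with normexp, where the camera direction turned. For IFN-alpha against IFN-beta the sterol median was -0.0296 with the slide block and the NRF2 median 0.0121 with normexp. Over all 27 lists, called or not, the slide block turned the sign of the median of 7 for IFN-alpha, 7 for IFN-beta and 7 for IFN-alpha against IFN-beta, and of 0 in each of IFN-gamma, type I against IFN-gamma and time. In that order of the 6 comparisons it ended 3, 8, 6, 0, 2 and 1 camera calls and added 4, 6, 2, 0, 0 and 1.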

Other observations

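The comparison by size of the IFN-alpha difference was chosen after the ratios above were seen. The ratio of the IFN-beta to the IFN-alpha difference was compared among genes of like size of the IFN-alpha difference, each interferon against the mock array of its own slide, so that IFN-alpha and IFN-beta share no control array. The mean over the times was used, and both times of an interferon share 1 mock array. For IFN-alpha differences of 1 to 2, 2 to 3, 3 to 4 and 4 or more, the median ratio was 0.540, 0.558, 0.520 and 0.449 over 3, 5, 11 and 26 genes of the antiviral and ISG15 lists. Over 9, 10, 3 and 1 genes of the MHC class I and GTPase lists it was 0.189, 0.243, 0.273 and 0.249. Over 135, 73, 36 and 49 genes well above background on all 8 arrays, members of these lists included, it was 0.122, 0.208, 0.331 and 0.347. The gap between the antiviral and ISG15 genes and all genes was smallest at 4 or more, where most of those list members lie. Genes shared by the 2 sets may narrow the gap there, so its size is not read as a result. What makes the lists differ was not tested, and each ratio rests on 1 array per interferon and time. IFN-alpha is measured on slide 1 and IFN-beta on slide 2, so a slide difference that varies with signal may enter the ratios.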
